A study of Homo sapiens with 6 samples.

How the data were processed

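RNA was isolated as total RNA and libraries were made with a KAPA RNA HyperPrep kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20.0.422, HISAT2 2.1.0, featureCounts 1.6.5 from Subread, and the build hg38, without saying how they were set. The deposited values are TPM (transcripts per total of 1000000). The name of the deposited table points to TPM made from counts adjusted with RUVs, a method that estimates unwanted variation from the differences between replicates and takes it out; its settings are not given in the sources used here. Such an adjustment lowers the spread between replicates, and so can lower p-values. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes may be shared.

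Columns were matched to samples by name, and groups were taken from the genotype in the labels. For 99.98% of genes (26480 of 26485) the deposited TPM values were whole multiples of a common step within a tolerance of 1e-06, and these multiples are called adjusted counts here. Symbols were matched to GENCODE 29 and a RefSeq table of GRCh38 (24536 by symbol and 757 by an older symbol, with 1084 unmatched), from which positions come. To protect privacy, 108 genes were left out of every table and test. A check for mixed-up samples was made only as a count, and 3 of 6 libraries did not match the labels as 1 line.

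Genes with at least 1 TPM in at least 3 of the 6 samples were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (eBayes with a trend, not robust, 2-sided), and called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene comes from limma. A fold change on this scale understates the change of genes at low TPM. Means and SDs are of TPM, with knockout replicates 2 and 3 as 1 sample; the test itself used all 6 samples, as set beforehand. Of 37 gene lists, 32 had at least 5 tested members and were tested with camera (preset correlation 0.01, and estimated) and fry, adjusted over the lists; under the alternatives below camera used the preset correlation only. On simulated data with 13986 genes, 3 samples against 3 and a dispersion of 0.01, the test called 0 of 50 genes changed 1.25-fold, 23 of 50 changed 1.5-fold, 45 of 49 changed 2-fold, 49 of 49 changed 4-fold, and 11 unchanged genes. The simulated samples varied independently and had no such adjustment, so these rates need not hold for the deposited values. In those, PKD2 was called at a 1.20-fold change.

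The tests, lists, rule for named genes and 18 alternatives were fixed before the data were examined. Genes named are PKD1, PKD2, PKHD1 and the PKD1 pseudogenes with values; the 8 higher and 8 lower genes with the largest log2 difference among those called, with a mean of at least 5 TPM, groups that do not overlap and an approved symbol; and, per list, the 2 called members with the largest change plus the one with the largest change the other way. HLA genes that this rule names are left out for privacy, and some other genes that it names are not reported here. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 TPM, median-of-ratios and quantile scaling, a replicate block, no trend, robust, array weights (statmod 1.5.0), protein-coding genes only, a trend on GC content and length taken out (97.2% of genes tested had both), and leaving out each sample. The test for raw counts was not run, since the values are TPM. The trend on GC content and length was set beforehand for the total count alone. Added after seeing the data were that trend for all other results, the direction without variation as a covariate, knockout replicates 2 and 3 averaged, voom on the adjusted counts, and knockout replicate 1 alone, where the lone sample is assumed to vary like the wild type. Figures were drawn with matplotlib 3.10.9.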

Results

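RNA-seq compared human ureteric bud tip cells labelled PKD1+/+ and PKD1-/-, PKD1 being the gene for polycystin 1 that is mutated in most autosomal dominant polycystic kidney disease. Ureteric bud tip cells are the kidney progenitors that give rise to the collecting ducts. They were made from the induced pluripotent stem cell line 1383D2 and were either PKD1+/+ (wild type, 3 samples) or PKD1-/- (knockout, 3 samples), per the labels. The cells were cultured for 6 weeks, the first week with 6 factors on soft hydrogel and then with a passage each week for 5 weeks. Each sample held a TPM value for 26485 genes, of which 13812 to 14037 stood at 1 TPM or more. Vimentin (VIM) was the highest gene in each wild-type sample and ACTB in each knockout sample. Whole adjusted counts behind the TPM values summed to between 31998081 and 32961352 per sample; these are counts after the authors' adjustment, so the depth of the reads themselves is unknown.

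Features of the samples bear on every value that follows. In a check for mixed-up samples, 3 of the 6 libraries did not match the labels' statement that all come from 1 line, so genotype and genetic background cannot be told apart here. Knockout replicates 2 and 3 differed by less than the sampling noise of counts over 13726 genes, with a chi-square of 0.804 per degree of freedom, against 13.2 and 16.4 for the pairs with knockout replicate 1. They were counted as 1 sample in each mean ± SD, so n = 2 for the knockout, although the labels name them as separate replicates. Knockout replicate 1 thus weighs as much in each knockout mean as replicates 2 and 3 together. Log2 differences and adjusted p-values come from the fit of all 6 samples, which counts these replicates separately. They can therefore differ from what the means give. The labels do not say whether replicates are separate cultures or clones, so p-values measure only the spread between these samples, which may be technical. Genes of liver and gut endoderm also stood apart in the libraries: 17 of 20 such genes, chosen after their values were seen, reached 1 TPM in knockout replicates 2 and 3, against 2 in knockout replicate 1 and 0 in each wild-type sample.

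The knocked-out gene was the first comparison, since it was meant as a check of the labels. PKD1, on the minus strand of chromosome 16 from 2088710 to 2135898 in GRCh38, was detected in all 6 samples. It stood at 10.96, 13.54 and 12.17 TPM in wild-type replicates 1, 2 and 3, and at 9.81, 8.58 and 8.16 TPM in knockout replicates 1, 2 and 3. PKD1 fell by 0.42 on the log2 scale (SE 0.10, limma adjusted p = 0.0103), from 12.2 ± 1.29 TPM (SD, n = 3) to 9.09 ± 1.01 TPM (SD, n = 2). PKD2, which encodes the channel partner of polycystin 1, rose from 83.0 ± 4.06 to 100.5 ± 1.75 TPM (log2 difference 0.27, adjusted p = 0.002). PKHD1, the fibrocystin gene of recessive polycystic kidney disease, rose from 9.97 ± 3.29 to 16.1 ± 1.504 TPM (log2 difference 0.64, adjusted p = 0.0323). That call ended without wild-type replicate 1 or 3 or knockout replicate 1 or 2 (adjusted p = 0.0828 to 0.105). It also ended with knockout replicates 2 and 3 averaged (limma adjusted p = 0.0608). PKD1 shares long stretches of sequence with its pseudogenes, of which PKD1P6 averaged 1.03 TPM in the wild type and 0.818 TPM in the knockout and PKD1P1 0.0833 and 0.139 TPM, so reads could be split among them. Gene-level TPM also does not show whether the transcript left in the knockout encodes a protein. A fall of 0.42 does not decide whether the labels are right, since 3089 of 14201 genes tested were lower in the knockout. With knockout replicate 1 alone against the wild type, the log2 difference of PKD1 was -0.29 and no longer passed (adjusted p = 0.19).

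**Figure D1:**
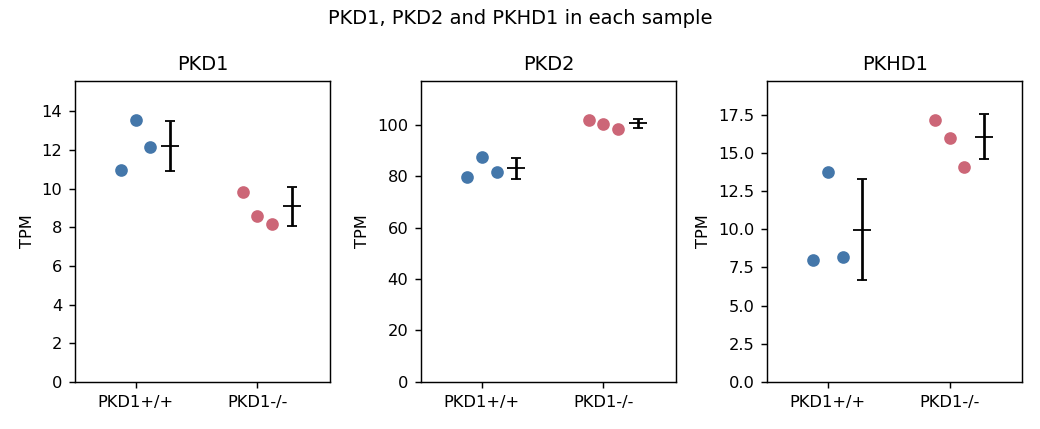
TPM of PKD1, PKD2 and PKHD1 (vertical axis) in the PKD1+/+ and PKD1-/- samples; points are samples, and the black bar with whiskers is the mean ± SD with n = 3 for the wild type and n = 2 for the knockout, whose replicates 2 and 3 count once. The 3 knockout samples lie between 8.16 and 9.81 TPM for PKD1, all below the wild-type samples, which lie between 10.96 and 13.54 TPM.

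Among genes with an approved symbol and a mean of at least 5 TPM, RELN, which encodes the secreted protein reelin, and CYP26B1, an enzyme that breaks down retinoic acid, were among the 8 largest rises. RELN rose from 0.0704 ± 0.0255 TPM to 50.4 ± 43.9 TPM (log2 difference 5.59, adjusted p = 0.000337), and CYP26B1 from 1.32 ± 0.212 to 52.5 ± 11.2 TPM (4.59, adjusted p = 6.88e-06). RELN stood at 19.3 TPM in knockout replicate 1 and at 79.6 and 83.2 TPM in replicates 2 and 3, which hold most of the endoderm transcripts; with replicate 1 alone the log2 differences were 4.25 for RELN and 4.30 for CYP26B1. The non-muscle myosin gene MYH14 rose by 3.95, the fatty acid transporter gene CD36 by 3.69, the homeobox genes EMX1 and HOXA5 by 3.66 and 3.46, and MRS2, a mitochondrial magnesium channel gene, by 3.39 from 55.2 to 574.5 TPM. Among the 8 largest rises is also CD99, which lies in a region shared by the sex chromosomes and is given without values. The largest fall among the same genes was that of CHCHD2, a mitochondrial protein gene, from 343.9 ± 18.4 TPM to 0.470 ± 0.369 TPM (log2 difference -7.98, adjusted p = 8.46e-07). LDOC1 fell too, with a log2 difference of -7.30, as did the neutrophil chemokine gene CXCL5 (-6.22), THEM6 (-5.72), the glutaminyl cyclase gene QPCT (-5.48) and the troponin gene TNNT1 (-5.04). SLC15A4, a lysosomal transporter gene, averaged 32.1 TPM in the wild type and was listed at 0 in each knockout sample. MIR6723 fell by 7.23, but its sequence is near-identical to mitochondrial sequence and its value is uncertain.

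Of 14201 genes tested, 8080 differed between PKD1-/- and PKD1+/+ cells, 4991 higher and 3089 lower in the knockout, and 949 differed at least 2-fold (475 higher, 474 lower). With samples rescaled by median-of-ratios factors, 3819 were higher and 3807 lower. With knockout replicates 2 and 3 averaged into 1 sample, 6195 genes passed, and with knockout replicate 1 alone, without the libraries that hold most of the endoderm transcripts, 3967 passed (2377 higher, 1590 lower); both were chosen after seeing the data. On the first principal component, which held 82.2% of the variance, the wild-type samples lay between -36.6 and -32.1 and the knockout samples between 29.8 and 37.2.

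Genes of glycolysis and the hypoxia response fell together in the knockout. Of 23 members tested, 21 fell and 0 rose over all genes tested, and 21 were called when adjusted over the list alone; the median log2 difference was -1.44. The fall was smaller in knockout replicate 1, with a median of -0.75 against the wild-type mean, than in replicates 2 and 3, which hold most of the endoderm transcripts (-1.78 and -1.88); all 23 members stood higher in replicate 1 than in both others, a comparison chosen after the values were seen. CA9, a carbonic anhydrase induced by hypoxia, fell by 4.11 from 18.4 ± 2.84 to 0.178 ± 0.213 TPM, and BNIP3, a mitophagy receptor gene, had a log2 difference of -3.33, from 201.2 ± 38.7 to 30.9 ± 27.6 TPM. GAPDH, chosen after its values were seen, fell from 5280 ± 219.7 to 3402 ± 666.9 TPM. The list passed camera with the preset correlation (adjusted p = 2.45e-08), but not with the correlation among its members estimated from these samples (adjusted p = 0.743 with an estimated correlation).

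Genes of cyst injury and inflammation also fell: 13 of 14 tested members were lower and 1 higher, and all 14 were called when adjusted over the list alone. Besides CXCL5, LCN2, a marker of tubular injury, fell by 3.01 from 44.5 ± 4.47 to 4.53 ± 0.410 TPM. SPP1, which encodes osteopontin, was the exception and rose from 27.8 ± 5.53 to 101.2 ± 9.99 TPM (log2 difference 1.88). The list passed camera (adjusted p = 4.52e-08; adjusted p = 0.642 with an estimated correlation).

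Cell cycle genes rose by small amounts. Of 23 tested, 22 were higher and 0 lower, 22 also when adjusted over the list alone, with a median log2 difference of 0.44. RRM2, a subunit of ribonucleotide reductase, rose from 81.2 ± 3.003 to 147.0 ± 6.88 TPM (0.86), and the mitotic kinesin gene KIF20A from 37.9 ± 2.56 to 68.7 ± 2.93 TPM (0.83). The list passed camera (adjusted p = 6.57e-07; adjusted p = 0.526 with an estimated correlation). Among inhibitors of cyclin-dependent kinases, 3 of 5 tested rose and 0 fell (3 adjusted over the list alone), CDKN1B by 0.65 and CDKN2D by 0.50. CDKN2D did not pass without knockout replicate 2 or 3 (adjusted p = 0.0599 and 0.0515). Nor did it pass with knockout replicates 2 and 3 averaged (limma adjusted p = 0.0553). The list did not pass camera (adjusted p = 0.465).

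Retinoid response genes were the fourth list to pass: 9 of 11 tested members rose and 1 fell, and 11 were called when adjusted over the list alone. CYP26B1 was among the rises, whereas STRA6, a receptor that takes up retinol, fell from 69.3 ± 2.98 to 40.9 ± 1.55 TPM (log2 difference -0.73). The list passed camera with adjusted p = 0.026 (adjusted p = 0.743 with an estimated correlation), and did not pass among genes with a mean of at least 5 TPM (adjusted p = 0.165).

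**Figure D2:**
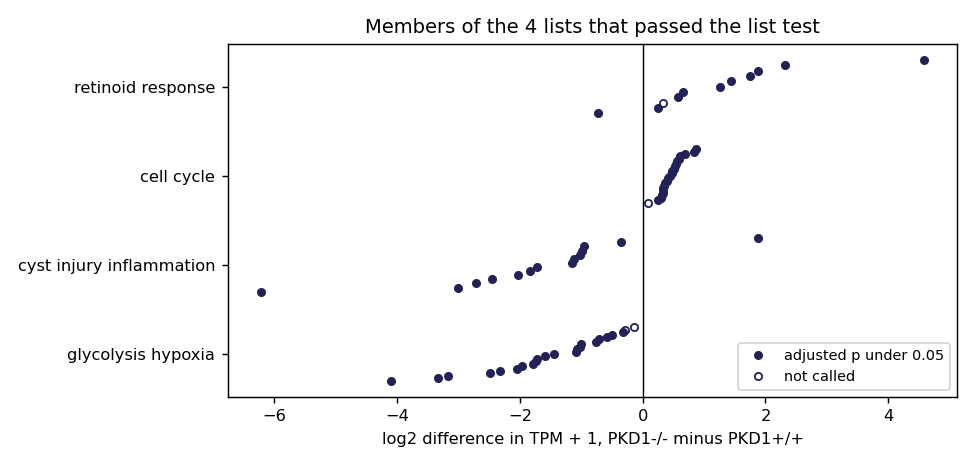
Log2 difference in TPM + 1 (horizontal axis, PKD1-/- minus PKD1+/+) of each tested member of the 4 gene lists that passed camera; filled points passed the test of single genes and open points did not. The glycolysis and hypoxia genes have a median of -1.44 and the cell cycle genes a median of 0.44.

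Markers of the ureteric bud moved in both directions. Of 13 tip genes tested, 4 rose and 5 fell (9 adjusted over the list alone). The receptor tyrosine kinase gene RET rose from 114.3 ± 19.6 to 161.3 ± 19.3 TPM (0.46), while the GDNF co-receptor gene GFRA1 fell from 71.7 ± 4.80 to 44.3 ± 11.7 TPM (-0.79), as did ETV4 (-0.50) and ETV5 (-0.61); RET, ETV4 and ETV5 were chosen after their values were seen. Of 19 bud epithelium genes, 9 rose and 4 fell (13 adjusted over the list alone), with EMX1 and CALB1 (2.57) among the rises. Neither list passed camera (adjusted p = 0.465 and 0.979).

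Markers of other epithelia of the kidney and lower tract were mostly higher. Among collecting duct principal cell genes, 5 of 9 tested rose and 0 fell (5 adjusted over the list alone); the transcription factor gene ELF5 rose from 22.1 ± 8.73 to 137.4 ± 23.9 TPM (2.69) and the sodium channel subunit gene SCNN1G from 0.0309 to 3.74 TPM (2.22). Among urothelium genes, 7 of 8 rose and 1 fell (8 adjusted over the list alone); SHH rose by 2.44 and UPK2 by 2.09, and the keratin gene KRT17 fell by 1.55. For the differentiated nephron, 4 of 6 rose and 2 fell (6 adjusted over the list alone), with LRP2 (1.70) up and CUBN (-0.68) down. None of the 3 passed camera (adjusted p = 0.129, 0.0967 and 0.724), though the urothelium list passed with median-of-ratios scaling (adjusted p = 0.0319) and with the trend on GC content and length taken out (adjusted p = 0.0396), both with the preset correlation (adjusted p = 0.743 with an estimated correlation). Most of the liver and gut transcripts were in knockout replicates 2 and 3. Knockout replicate 1, which held few of them, still stood above every wild-type sample for each rise named here. Its values were 120.5 TPM for ELF5, 3.50 for SCNN1G, 5.64 for SHH, 20.3 for UPK2 and 23.9 for LRP2. It stood below every wild-type sample for both falls, KRT17 (91.9 TPM) and CUBN (10.8 TPM).

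In the lists set beforehand, few markers of other cell types were high enough to be tested. For intercalated cells, 3 of 4 tested rose and 1 fell, with CA2 up by 1.85 and the proton pump gene ATP6V1B1 down (log2 difference -2.70). For nephron progenitors 2 of 4 rose (OSR1 1.24, CITED1 0.93), for neural genes 2 of 3 (DCX 1.36, NEFL 1.05), for endothelium 1 of 1 (ESAM 1.54), and for pluripotency 2 rose and 1 fell of 4 (SOX2 1.47, and ZFP42 from 1.95 TPM to a listed 0). All of these calls held when adjusted over the list alone, and each list had fewer than 5 tested members, too few for a list test. Stroma genes were called 3 up and 3 down of 6 (6 adjusted over the list alone): MEIS1 rose by 0.99, ACTA2 by 0.92, and VIM fell from 7026 ± 382.6 to 4212 ± 1131 TPM; the list did not pass camera (adjusted p = 0.979).

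Signalling lists held calls in both directions, and none passed camera as set beforehand. In the Notch list 7 of 11 rose and 1 fell (8 adjusted over the list alone), with HEYL (1.09) and HES1 (1.00) up and JAG2 (-0.61) down (camera adjusted p = 0.129, and 0.00813 with knockout replicate 1 alone; adjusted p = 0.901 with an estimated correlation). In the ERK, GDNF and FGF response list 6 of 18 rose and 9 fell (15 adjusted over the list alone), with PHLDA1 (-0.85) and SPRED3 (-0.75) down and DUSP4 (0.48) up. In the cAMP list 5 of 14 rose and 5 fell (10 adjusted over the list alone), RGS2 (2.59) and AREG (-1.72) among them. In the BMP and TGF-beta list 5 of 14 rose and 2 fell (7 adjusted over the list alone); ID1 rose from 68.0 ± 14.4 to 288.6 ± 15.0 TPM (2.07), SMAD7 rose by 1.12 and TGFB1 fell by 0.68. In the Wnt target list 3 of 14 rose and 4 fell (7 adjusted over the list alone; BMP4 1.23, AXIN2 -0.66), in the planar polarity list 7 of 17 rose and 3 fell (10 adjusted over the list alone; WNT5A 1.38, FAT4 1.09, CELSR3 -0.97), and in the YAP target list 5 of 16 rose and 2 fell (4 adjusted over the list alone; CRIM1 0.80, FJX1 -0.49). The call of DUSP4 ended without wild-type replicate 1 or 3 or knockout replicate 2 or 3 (adjusted p = 0.068 to 0.0953). That of AXIN2 ended without wild-type replicate 1 or 3 or any 1 of the knockout replicates (adjusted p = 0.0574 to 0.102). Both calls also ended with knockout replicates 2 and 3 averaged (limma adjusted p = 0.091 for DUSP4 and 0.0683 for AXIN2).

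Genes of matrix, adhesion and transport were split as well. In the extracellular matrix list 7 of 34 rose and 12 fell (19 adjusted over the list alone); LAMB3 (-2.76) and TNC (-1.63) fell, and VCAN rose by 1.19. Its camera adjusted p was 0.0656, but the list passed without wild-type replicate 1 (0.045) or 2 (0.0453) or knockout replicate 1 (0.0371) and with array weights (0.0267). Each time its members lay lower relative to the other genes tested, and all were with the preset correlation (adjusted p = 0.901 with an estimated correlation). The list's own median log2 difference was -0.04, and 15 members were not called. In the integrin and adhesion list 6 of 18 rose and 7 fell (14 adjusted over the list alone; CD44 -1.31, ITGB6 -0.78, ITGA1 0.63), and in the tight junction list 8 of 17 rose and 5 fell (13 adjusted over the list alone; CLDN8 1.61, CLDN6 1.19, CLDN3 -0.88). Among ion and fluid transport genes 10 of 21 rose and 6 fell (16 adjusted over the list alone), with the potassium channel genes KCNE3 up (2.04) and KCNN4 down (-2.54). Among primary cilium genes 7 of 32 rose and 5 fell (11 adjusted over the list alone; FOXJ1 1.45, IFT46 -0.37), and among genes of polycystins and cystic disease 4 of 14 rose and 2 fell (6 adjusted over the list alone).

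Metabolic and stress lists other than glycolysis and hypoxia did not pass camera as set beforehand, but 3 of them passed under other settings. Respiration passed with no filter (adjusted p = 0.0296), array weights (0.0267), the trend on GC content and length taken out (0.0472) and without knockout replicate 1 (0.0219), all with the preset correlation (adjusted p = 0.743 with an estimated correlation). Cholesterol synthesis passed without knockout replicate 1 (0.0371), and the unfolded protein response without wild-type replicate 2 (0.0453) and with knockout replicate 1 alone (0.0348), again with the preset correlation (adjusted p = 0.901 with an estimated correlation for each list). Cholesterol synthesis genes rose in 10 of 17 cases and fell in 2 (12 adjusted over the list alone; MVK 0.53, IDI1 0.52), and respiration genes rose in 16 of 22 cases and fell in 1 (17 adjusted over the list alone; CPT1A 1.13, PPARGC1A 0.47, UQCRC2 -0.18; camera adjusted p = 0.0648). In the unfolded protein response list 3 of 17 rose and 9 fell (12 adjusted over the list alone; CHAC1 -1.12, PSAT1 1.00), and in the p53 and apoptosis list 6 of 16 rose and 3 fell (9 adjusted over the list alone; BBC3 -0.75, GDF15 -0.64, SESN1 0.59). In the dissociation stress list 4 of 10 rose and 4 fell (8 adjusted over the list alone; JUNB -1.05, ATF3 -1.01, HSPA1B 0.74), and in the interferon list 3 of 14 rose and 6 fell (9 adjusted over the list alone; OAS1 1.27). HOX cluster genes rose in 13 of 22 cases and fell in 6 (19 adjusted over the list alone), HOXA5 among the rises and HOXD3 (-0.91) among the falls, and HOXA6, HOXA7 and HOXA9 were listed at 0 in each wild-type sample. Imprinted genes rose in 4 of 11 cases and fell in 5 (9 adjusted over the list alone; MEST 1.05, IGF2 0.97, NNAT -0.84). The median, mean and camera direction differed in sign for 7 lists: cAMP response, imprinted genes, ion and fluid transport, p53 and apoptosis, primary cilium, stroma and tight junctions.

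**Figure D3:**
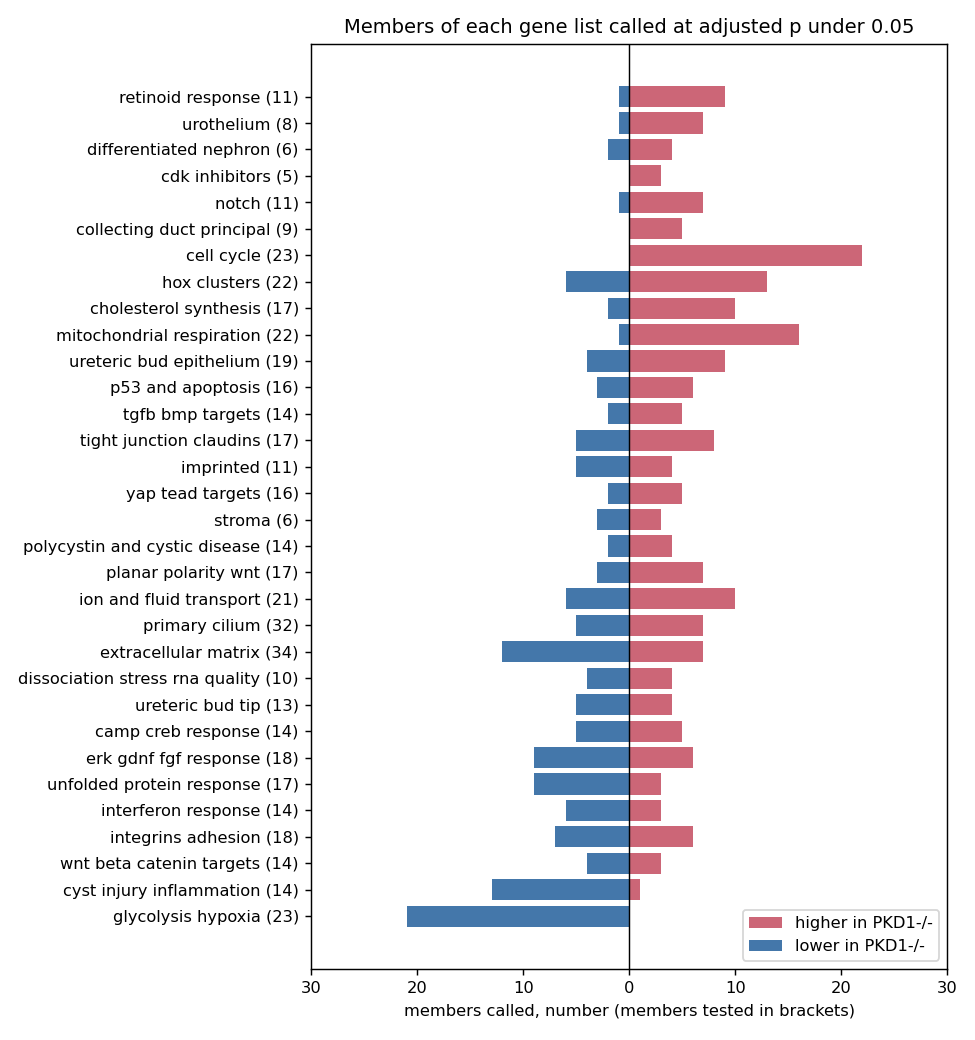
Number of members called higher (right of 0) and lower (left of 0) in PKD1-/- cells for each of the 32 gene lists with at least 5 tested members, ordered by median log2 difference; the number tested is in brackets. Glycolysis and hypoxia shows 21 of 23 members lower, and cell cycle 22 of 23 higher.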

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

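The count of differing genes stayed within 1.5 times of 8080 under each alternative set beforehand, and no named gene changed direction under any; array weights, whose estimate stopped before its tolerance and gave 0.224 and 7.68 to knockout replicates 2 and 3, gave the highest count, 10279. Leaving out 1 sample gave 5989 to 8532 genes and 4 to 7 lists. The replicate block gave 7618 genes. Same-numbered samples deviated with correlations of -0.04, 0.29 and 0.16, against -0.255 to 0.176 for samples with unlike numbers. These deviations come after the authors' adjustment, so they do not decide whether the numbers pair the samples. A mean of at least 5 TPM left 533 of 11338 genes tested differing at least 2-fold, against 949 of 14201, so genes of low TPM held many of the 2-fold calls. That count was 1348 with a pseudocount of 0.1, and 1381 with voom, which was chosen after seeing the data. Against 4 lists with the preset correlation, camera with an estimated correlation called 0 and fry, which asks only whether a list moves, 21. Of the alternatives chosen after seeing the data, the trend on GC content and length taken out gave 3821 higher and 3864 lower genes (only its total was set beforehand), the removed direction as a covariate gave 6740 genes, averaging knockout replicates 2 and 3 gave 6195, and voom 7852. Knockout replicate 1 alone gave 3967 genes, 2377 higher and 1590 lower, with PKD1 at -0.29 (adjusted p = 0.19); fewer samples entered that fit. Of the other named gene values over these settings, 2249 kept their side of the threshold and 35 no longer passed. The counts of members higher or lower per list were less stable: 1481 stayed within 1.5 times of the main count and 147 did not. The depth of the reads is not known, so what it limits was not tested.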

Other observations

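The gene families, the added lists and the on and off genes here, and the tests on cell line, PKD1, repeated deposit and removed variation, were chosen after the results were seen. Genes on in every sample of 1 group (at least 5 TPM) and off in every sample of the other (under 0.5 TPM) numbered 36. Of these, 27 were on in the wild type, including LDOC1, THEM6, CA9 and 6 zinc finger genes named ZNF. The other 9 were on in the knockout, including RELN, HOXA5, MEIS2 and SHH. Over all 472 ZNF genes tested, 2.12% were at least 2-fold lower, against 3.38% of other genes. Clustered protocadherin genes, which mark neighbouring cells apart, moved both ways, with 8 of 25 called higher and 7 lower; 6 were at least 2-fold higher (24%, against 3.31% of other genes; Fisher's exact test, adjusted p = 0.000932 over 20 tests), PCDHGB4 with a log2 difference of 2.74 among them, and 2 at least 2-fold lower (8%, against 3.33%; adjusted p = 0.368). Of 21 cytochrome P450 genes, 10 were called higher and 3 lower, with 0 at least 2-fold lower and 6 at least 2-fold higher (adjusted p = 0.00048, Fisher's exact test), the latter including CYP1A1 (2.75), CYP1B1 (1.17) and CYP27A1 (2.39). CYP26B1 (4.59), given above among the largest rises and the retinoid genes, is also a cytochrome P450 gene, so this result is not separate from those. Targets of NF-kB outside the fixed lists fell in 17 of 19 cases (camera adjusted p = 6.67e-12, and 0.0382 with an estimated correlation), CXCL6 (-2.84) and IL1B (-2.73) among them. That list holds CXCL2, CXCL3 and CXCL6, which lie near CXCL5 on chromosome 4. Genes of the DNA replication fork, another added list, rose in 14 of 16 cases and fell in 1 (camera adjusted p = 7.16e-05, and 0.0511 with an estimated correlation). These lists and families were chosen after the results were seen, so their p-values are not independent support. Fisher's exact test also takes neighbouring genes of a family as independent.

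Transcripts of liver and gut endoderm were found in part of the knockout. APOA2 stood at 0 TPM in each wild-type sample and in knockout replicate 1, and at 43.9 and 79.8 TPM in knockout replicates 2 and 3. The 20 genes summed to 196.5 and 291.9 TPM in those libraries, to 5.91 TPM in knockout replicate 1 and to between 0.890 and 1.76 TPM in the wild type. ALB, AHSG and TF stayed under 0.3 TPM in all 6 samples.

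Candidates for the breadth of the difference between the groups are a difference in cell line or donor and the loss of PKD1. In the check for mixed-up samples, 3 of 6 libraries parted from the others along the groups. That points to a difference in cell line or donor between the groups, whose share of the 8080 genes is not known. PKD1 fell by 0.42, but loss of PKD1 cannot be told apart from that difference, because both follow the groups. Of the 10 splits of the 6 samples, 1 gave as many genes, the real one with 8080; the highest other split gave 2, and 10 splits are too few for a share under 0.05.

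The fall of glycolysis and hypoxia genes is not accounted for by GC content and gene length: with that trend taken out, the median of the list was -1.50 (error 0.27). Lower HIF activity in the knockout cultures is a hypothesis that a further list of genes left standing, without testing it independently. HIF targets with no part in glycolysis had a median of -0.98 (error 0.16), and 18 of 22 fell while 1 rose. This list was added after the results were seen, and the fixed list already held hypoxia genes such as CA9 and BNIP3. In the added list ANGPTL4 (-2.11) and P4HA1 (-1.59) fell and CITED2 (0.21) rose. DDIT4 (-0.07), RAB20 (-0.32) and PPP1R3C (1.05) did not pass the test. That list passed camera (adjusted p = 5.65e-08; adjusted p = 0.127 with an estimated correlation), and its median was -0.72 in knockout replicate 1 against -1.20 and -1.30 in replicates 2 and 3. Oxygen supply, colony density and the difference in background were not measured and stay open.

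Knockout replicates 2 and 3 were nearly alike. A first criterion for a repeated deposit of 1 library, a chi-square per degree of freedom at or under 1 over all genes, was met at 0.804, and was replaced after that value was seen by one on genes with a mean adjusted count above 10000, which was not met at 4.16 (error 0.45). Both values come after the adjustment and set single samples against sampling noise, so neither decides, and a repeated deposit stays open. Of the 4 within-group directions of variation, 1 had a variance of 7.35e-05 times the sampling noise, with weights of 0.73 and -0.66 on these samples and -0.15 on wild-type replicate 2. This is consistent with RUVs having removed 1 direction, in which case the likeness comes from the adjustment and the p-values are too small.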
